A study of Mus musculus with 39 samples.

How the data were processed

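Small RNA libraries from the hearts of wild-type FVB/NJ mice were compared by sex and by age. Per the labels, ventricular apexes were snap-frozen and RNA was taken up in Trizol, while the tissue tag reads whole heart. Libraries were made with the Illumina TruSeq small RNA kit, which ligates adapters to both ends of short RNAs, copies them into cDNA, amplifies them in few cycles and selects them by size. They were sequenced on HiSeq 2000 instruments. Ligation and amplification favour some sequences over others, so levels of different miRNAs within a library are not directly comparable, and without molecular identifiers a count is a read and not a molecule.

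The deposited values were whole-number counts per mature miRNA arm, 1 file per library. Per the submitters' processing notes the genome build was GRCm38, and DESeq and edgeR were named there without a role or a version. The aligner, the annotation and the treatment of reads that match several loci are not given in the sources used here. The male files listed 1545 features and the female files 1451, with 1312 in both and 1684 in either; the 233 features of male files alone and the 139 of female files alone summed to at most 11 and 8 counts, and a feature not listed was taken as 0. Each deposited name gave a transcript and coordinates. Of the 1684 features, 1664 named a transcript found in the GENCODE annotation of GRCm38; the coordinates overlapped that transcript for 1661, and the strand given was that of the transcript for 1661. Among the 1684, 185 features were deposited as antisense to a miRNA gene and held 12.53% of counts; 48 of them, with nearly all of those counts, lay on a miRNA gene of the other strand and were named after it. The files held no class of RNA other than miRNA features, so an alternative with all features was not run. miR-122 was on the list of features to name and was not tested in any comparison.

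Total counts ran from 1788245 to 14563754 per library. A count of 0 allows a level of up to 3 counts, which is 0.206 to 1.68 CPM by library. Shares in single libraries are given with 95% Wilson intervals. Intervals and floors cover counting error only.

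Groups came from the sex and age in the labels. The tests, the samples in each, the rule for named arms, 16 lists of miRNAs and most of the alternative settings were fixed before the data were examined. Sex was tested at 6 weeks (12 male, 6 female libraries), and over 6 to 8 weeks with age as a factor (17 male, 11 female). Age was tested as a slope per week in males of 4 to 8 weeks (22 libraries) and in females of 6 to 9 weeks (16 libraries), and the difference between the slopes of the sexes over 6 to 8 weeks as a sex by age term. The single library of 16 weeks was left out of the male slope, which it alone would have set, and its values are given without a test.

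The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors, on arms with a CPM of 5 or more in at least 5 of the libraries fitted. Benjamini-Hochberg adjustment ran over the arms tested, and an adjusted p under 0.05 was called. Values in the text are log2 differences, or log2 slopes per week, with their SE. Levels in CPM are scaled by TMM factors, and shares are percent of all counts of the library. Lists with 3 or more tested arms were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with its preset correlation of 0.01, which compares a list with the other arms, and beside it with an estimated correlation and with fry, which tests whether a list moves on balance one way without comparing it with other arms; Benjamini-Hochberg adjustment ran over the lists. The lists were muscle and heart muscle, red blood cell, white blood cell, endothelial, smooth muscle, fibroblast and matrix, fat tissue, epithelial and lung, liver and brain, the let-7 family, the miR-17 to miR-92 clusters, the miR-15 and miR-16 family, the miR-30 family, the Dlk1-Dio3 imprinted cluster, X chromosome miRNAs, and cardiac hypertrophy and stress miRNAs. Shares of counts per list were compared at 6 weeks by a two-sided exact permutation test over 18564 regroupings of the 18 libraries, and, as an alternative added after the data were seen, over the 300 regroupings within the library sets that held both sexes. The spread at 6 weeks was the CV of TMM-scaled CPM.

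The arms to be named were the 10 most abundant; per comparison the 10 largest rises and 10 largest falls among called arms with a mean of 20 CPM or more, or the 5 with the smallest p where fewer than 5 were called; the 2 most abundant members of each list; the arms of miR-208a, miR-208b, miR-499, miR-1a, miR-133a, miR-451a and miR-126a; and the 5 most and 5 least variable arms. Any other arm is said to have been chosen after its values were seen, except copies and relatives of named arms, which were also taken up after the data were seen.

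The labels give no batch or date. Libraries were therefore grouped after the data had been seen, from the share of counts that each locus received among loci with one identical mature sequence. The sequence is the same at each such locus, so the division was assumed to depend on how reads were assigned or on which ends they have. It was taken as a mark of a common preparation or processing. Whether it also follows the output of the loci themselves was not tested. Copies with at least 100000 counts for the rarer locus entered, and hierarchical clustering (cluster 2.1.8.1 for silhouettes) into 7 sets was used, with 6 and 8 sets and looser copy rules as alternatives.

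Other alternatives were DESeq2 1.42.0, limma-voom, median-ratio factors, total counts without factors, no filter, a filter at 50 CPM, robust dispersion, depth as a covariate, 1 surrogate variable (sva 3.50.0), the 5 most abundant arms left out, the replicate number as a block, other age ranges, and each library left out in turn. Alternatives added after the data were seen were the library set as a term or alone, copies of one or a near-identical mature sequence summed (arms that share bases 3 to 20), each library left out of the list test, the 4 libraries left out in which 1 arm took over 40% of counts, and a GC trend removed from each library. Each comparison was also repeated on 99 other splits of its libraries drawn at random, which with the real one makes 100.

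The tests were tried on simulated counts drawn from the real means, library sizes and spread, with 200 arms changed by known amounts. edgeR recovered 63.1%, 92.3% and 100% of the arms changed by 0.5, 1 and 2 log2 units at 6 weeks (337 arms tested), and 63.6%, 98.5% and 100% over 6 to 8 weeks (354). For slopes of 0.25, 0.5 and 1 per week it recovered 76.9%, 98.5% and 100% in males (352) and 62.7%, 90.9% and 98.5% in females (334). For the difference between slopes it recovered 59.7%, 91.0% and 100% of those changed by 0.5, 1 and 2 (355). A shift given to the let-7 list was called by camera and fry in each of the 3 comparisons tested, with 0 of the other lists. The simulated arms were drawn independently and without library sets, and with 200 changed arms the adjusted threshold is easier to pass. The shares recovered are therefore not the power to find a lone change in the real libraries. The list check does not test the preset correlation of camera. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.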

Results

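Small RNA of the mouse heart was sequenced from wild-type FVB/NJ mice, an inbred laboratory strain. The series held 39 libraries, 23 from males and 16 from females. The male libraries came from mice of 4 weeks (2 libraries), 5 weeks (3), 6 weeks (12), 7 weeks (1), 8 weeks (4) and 16 weeks (1). The female libraries came from mice of 6 weeks (6 libraries), 7 weeks (3), 8 weeks (2) and 9 weeks (5). Each library was a list of counts per mature miRNA arm, the strand of the precursor hairpin that is kept as the short regulatory RNA. Total counts ranged from 1788245 to 14563754 per library, with a median of 8410768. The lowest total belonged to female_8wk replicate 2, and the next lowest was 3970178. The labels do not state that each library came from a separate animal, so p-values measure the spread between these samples. No pair of libraries of one group agreed within sampling noise: the smallest chi-square per degree of freedom over 105 pairs was 39.42.

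The 10 most abundant arms took 67.6% ± 4.70 (SD, n = 39) of all counts. miR-22-3p, an abundant miRNA of heart muscle (chromosome 11, 75463772 to 75463793, in an exon of Tlcd2; all coordinates are GRCm38), was the highest at 16.2% ± 3.90. miR-143-3p, known from vascular smooth muscle (chromosome 18, 61649199 to 61649219, between genes), took 13.5% ± 9.13. The muscle miRNA miR-133a-2-3p (chromosome 2, 180398437 to 180398458, between genes) took 7.59% ± 1.75. miR-486b-5p and miR-486a-5p, which are abundant in red blood cells, took 5.89% ± 3.73 and 5.38% ± 2.90; they lie on opposite strands of one locus on chromosome 8 (23142629 to 23142649 and 23142587 to 23142608, in introns of Gm15816 and Ank1), so the split between them is uncertain. miR-378a-3p, encoded in an intron of the mitochondrial regulator gene Ppargc1b (chromosome 18, 61397837 to 61397858), took 5.16% ± 6.82. Its mean and SD were raised by 1 library, female_7wk replicate 2, where it took 46.4%. The next arms were miR-27b-3p (4.53% ± 1.09; chromosome 13, 63300760 to 63300780), the endothelial miR-126a-5p (3.35% ± 0.868; chromosome 2, 26591365 to 26591385, in Egfl7), miR-30a-5p (3.32% ± 0.757; chromosome 1, 23272274 to 23272296) and miR-26a-2-5p (2.63% ± 0.441; chromosome 10, 126995543 to 126995564, in an intron of Ctdsp2). These shares are means over 39 libraries with their SD.

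In 4 libraries a single arm took over 40% of the counts. miR-143-3p took 43.6% in male_6wk replicate 2 (95% Wilson interval 43.507 to 43.593), 43.0% in male_6wk replicate 6 (42.973 to 43.042) and 43.6% in female_6wk replicate 1 (43.544 to 43.612). In female_7wk replicate 2, miR-378a-3p took 46.4% (46.322 to 46.395). The intervals cover counting error only. The other arm of each hairpin, chosen after its values were seen, was also high in these libraries: miR-143-5p lay 8.79-fold, 7.35-fold and 6.97-fold above the median of the remaining libraries of the set of each, and miR-378a-5p lay 15.1-fold above.

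**Figure D1:**
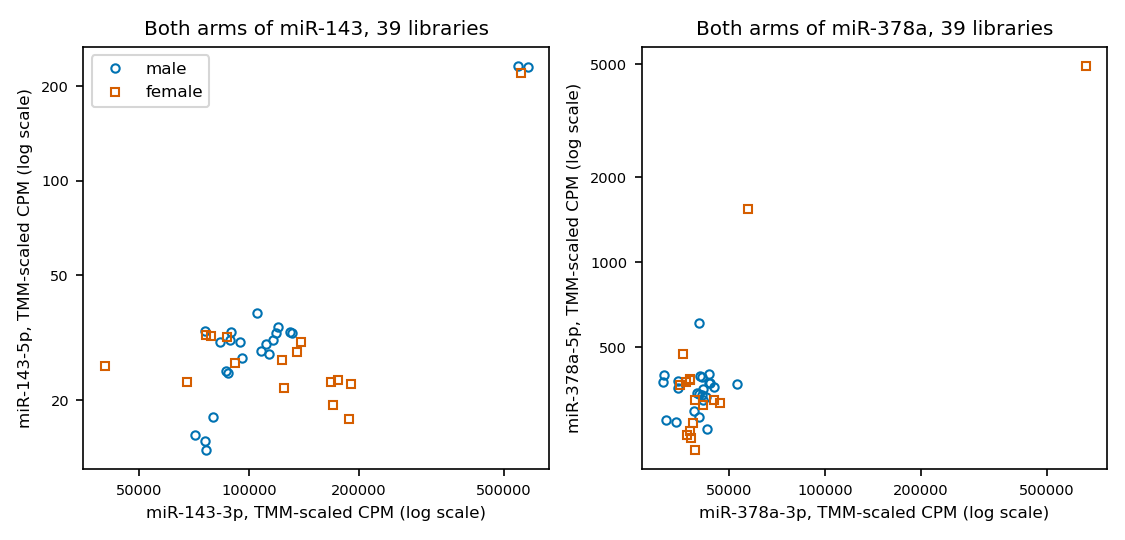
CPM (both axes logarithmic) of the 3p arm (horizontal) and the 5p arm (vertical) of the miR-143 and miR-378a hairpins, 1 point for each of the 39 libraries. Both arms were high together in 3 libraries for miR-143 and in 1 for miR-378a.

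Libraries also differed in how counts were divided between loci that encode one identical mature sequence. let-7a-5p, a member of the let-7 family that restrains growth and is high in adult tissue, comes from more than 1 locus; the let-7a-1 locus received 6.83% ± 0.369 of the pair's counts in 6 libraries and 33.2% ± 0.395 in 4 others. For miR-16-5p, a repressor of cell cycle genes, the miR-16-1 locus (chromosome 14, 61631936 to 61631957, in an intron of Dleu2) received 3.12% ± 0.415 and 21.4% ± 0.341 of the pair's counts in the same libraries. The shares of 8 such copies divided the 39 libraries into 7 sets of 6, 5, 8, 6, 4, 5 and 5 libraries. Set 1 held all 5 male libraries of 4 and 5 weeks and 1 female library of 6 weeks, sets 2 to 4 held libraries of 6 and 7 weeks, sets 5 and 6 held libraries of 7 weeks and older, and set 7 held the 5 female libraries of 9 weeks alone. The sets accounted for 64.7% of the variance of log2 levels over the tested arms, against 53.5% for the 10 groups of sex and age. Among 6-week libraries they accounted for 65.2%, and 100 random sets of the same sizes reached at most 43.9%. The sets were made from counts of these same libraries, so a share above that of random sets follows in part from how they were made. It does not show whether preparation, processing or the animals gave rise to the sets. Of the variance in age, 92.2% lay between sets. The library set was therefore entered as a term beside the fitted results, and shares of lists were also compared within sets. Levels given for one locus of let-7c-5p, let-7f-5p, miR-1a-3p, miR-16-5p, miR-26a-5p, miR-30c-5p, miR-125b-5p, miR-133a-3p, miR-181a-5p and miR-199a-3p are uncertain by locus.

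**Figure D2:**
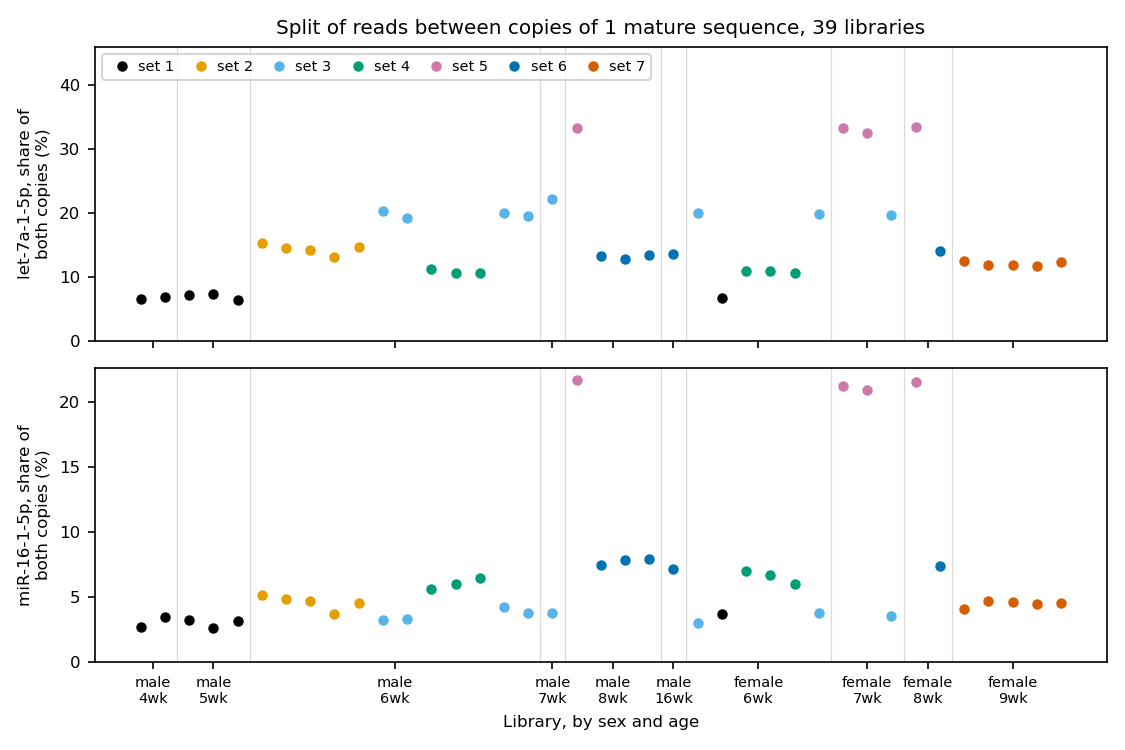
Percent of counts assigned to the let-7a-1 locus and to the miR-16-1 locus among loci with the same mature sequence, for each of the 39 libraries ordered by group and coloured by library set. Libraries of one group fell at separate levels, and the let-7a-1 share ran from a mean of 6.83% in set 1 to 33.2% in set 5.

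The sexes were compared at 6 weeks, where 12 male and 6 female libraries had the same age. No heart muscle miRNA passed the test. miR-208a-3p, encoded in an intron of the adult cardiac myosin gene Myh6 (chromosome 14, 54949072 to 54949093), differed by -0.02 ± 0.11 (log2 female minus male ± SE). miR-208b-3p, encoded in an intron of the slow cardiac myosin gene Myh7 (chromosome 14, 54975710 to 54975731), differed by 0.18 ± 0.15, and miR-499-5p, in an intron of Myh7b (chromosome 2, 155622893 to 155622913), by -0.04 ± 0.10. The differences were 0.05 ± 0.07 for miR-133a-2-3p, 0.22 ± 0.20 for miR-133a-1-3p and 0.48 ± 0.45 for miR-1a-1-3p, which are muscle miRNAs. The red blood cell miRNA miR-451a-5p differed by -0.64 ± 0.35, and the endothelial miR-126a-3p by -0.20 ± 0.12. edgeR called 0 of 339 arms (25 at an unadjusted p under 0.05; smallest adjusted p 0.478); DESeq2 called 0 (31 unadjusted) and limma-voom 0 (25 unadjusted). The 5 arms with the smallest p all had an adjusted p of 0.478: miR-212-3p, whose cluster is induced in cardiac hypertrophy (0.49 ± 0.14), the epithelial miR-200b-3p (-1.43 ± 0.44), miR-151-3p (0.40 ± 0.14), let-7j-5p (-0.96 ± 0.35) and miR-208a-5p (-0.33 ± 0.12). The 95% interval of the difference lay within 1 log2 unit of 0 for 297 of the 339 arms and within 0.5 for 161. With the library set as a term edgeR also called 0 (33 unadjusted), as it did within set 3 (0, 13 unadjusted) and within set 4 (0, 30 unadjusted).

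Of 16 lists of miRNAs, 1 differed between the sexes at 6 weeks. The list of miRNAs tied to cardiac hypertrophy and stress had 22 of 31 tested arms higher in females, with a median of 0.09 (camera adjusted p = 0.0384); none of its members was called by itself, over all arms or adjusted over the list alone. The adjusted p was 0.708 with an estimated correlation and 0.775 with the library set as a term, and the call also ended without male_6wk replicate 1, 2, 3 or 4 or female_6wk replicate 1, 2 or 6 (0.0548 to 0.0940). Its most abundant members pointed both ways, miR-27a-3p at 0.14 ± 0.08 and miR-21a-5p, which is raised in stressed and fibrotic heart, at -0.21 ± 0.08. In the other 15 lists no arm was called over all arms, and adjusted over the list alone 1 arm of the epithelial and lung list, miR-200b-3p, was lower in females. Of 13 muscle arms 6 were higher in females, with a median of -0.02 (camera adjusted p = 0.947), and muscle miRNAs took 9.68% ± 1.60 (SD, n = 12) of counts in males and 9.93% ± 1.75 (n = 6) in females (two-sided exact permutation p = 0.744). Of 7 red blood cell arms 6 were lower in females, with a median of -0.43 (camera adjusted p = 0.263). Their share was 9.08% ± 3.04 in males and 8.70% ± 2.48 in females (exact permutation p = 0.802); most of it was miR-486b-5p and miR-486a-5p, which differed by 0.11 ± 0.20 and -0.03 ± 0.17. Endothelial miRNAs took 4.37% ± 1.07 and 4.49% ± 0.969, and smooth muscle miRNAs 16.6% ± 12.6 and 17.96% ± 12.6. The smooth muscle means and SDs were raised by male_6wk replicates 2 and 6 and female_6wk replicate 1, dominated by miR-143-3p. In the last the share was 43.7%, against 11.04% to 13.7% in the other females. Over the 16 lists the smallest exact permutation p was 0.0867, for the miR-15 and miR-16 family (1.05% ± 0.251 in males, 0.858% ± 0.115 in females; adjusted p = 0.698). Regrouped only within sets 3 and 4, which held 7 of the male and 5 of the female libraries, the smallest exact permutation p was 0.107, for white blood cell miRNAs (adjusted p = 0.811). No share was called in either test.

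Over 6 to 8 weeks, with age as a factor, 17 male and 11 female libraries were compared. miR-871-3p, an X-chromosome miRNA known from testis, had the smallest p with a female minus male difference of 1.30 ± 0.40. This arm was low in the males of 4 to 8 weeks, at a mean of 2.50 CPM (0.693 to 7.84). It was followed by let-7j-5p (-0.86 ± 0.27), miR-1249-3p (0.77 ± 0.25), miR-151-3p (0.60 ± 0.21) and miR-181a-1-5p (0.27 ± 0.10); the smallest adjusted p was 0.354. edgeR called 0 of 346 arms (46 unadjusted), DESeq2 0 (54 unadjusted) and limma-voom 0 (40 unadjusted). Scaling by total counts alone moved the median difference by -0.14, and left 0 arms called.

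The age of the male libraries was then compared with miRNA level from 4 to 8 weeks, as a slope in log2 per week over 22 libraries. miR-208b-3p, whose host gene Myh7 is the slow myosin that the mouse ventricle replaces with Myh6 after birth, fell from 1446 ± 39.5 CPM (SD, n = 2) at 4 weeks to 517 ± 67.2 (n = 4) at 8 weeks. All 4 libraries of 8 weeks (453 to 596 CPM) lay below all 5 of 4 and 5 weeks (1189 to 1474 CPM), and the slope was -0.39 ± 0.05 per week (SE; edgeR adjusted p = 1.6e-05). The other myosin-encoded miRNAs were not called: miR-208a-3p had a slope of 0.03 ± 0.08 and miR-499-5p of -0.07 ± 0.07. miR-29a-3p and miR-29c-3p, repressors of collagen and other matrix genes (chromosome 6, 31062673 to 31062694, and chromosome 1, 195037600 to 195037621), rose 2.73-fold and 2.81-fold over the 4 weeks. miR-29a-3p reached 3269 ± 659 CPM (n = 4) at 8 weeks from 1204 ± 19.2 (n = 2) at 4 weeks. All 4 libraries of 8 weeks (2717 to 4203 CPM) lay above all 5 of 4 and 5 weeks (at most 1673). miR-127-3p, a maternally expressed miRNA of the imprinted Dlk1-Dio3 region (chromosome 12, 109592888 to 109592909), fell from 2607 CPM (mean, n = 2; range 2600 to 2615) to 778 ± 165 (n = 4), with a slope of -0.47 ± 0.09 (adjusted p = 0.000663).

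**Figure D3:**
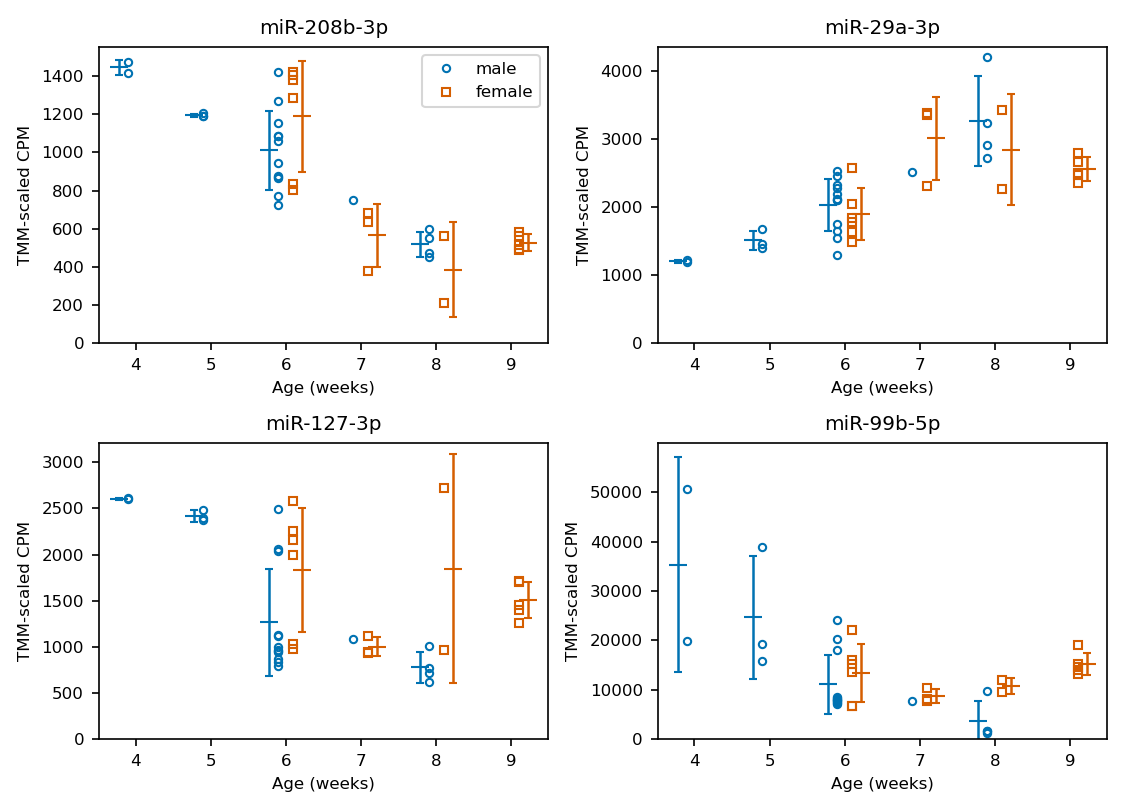
Level (CPM after TMM scaling) of miR-208b-3p, miR-29a-3p, miR-127-3p and miR-99b-5p against age in weeks, males and females apart; points are libraries, and markers with bars are group means ± SD. In males miR-208b-3p went from 1446 CPM at 4 weeks to 517 at 8 weeks and miR-29a-3p from 1204 to 3269; the library of 16 weeks is not drawn.

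In all, 121 of 346 arms changed with age in males, 47 rising and 74 falling (154 at an unadjusted p under 0.05). Scaled by total counts alone, 61 rose and 35 fell. Among arms with a mean of 20 CPM or more, the largest rises beside the miR-29 arms were in miR-16-1-5p (0.72 ± 0.09 per week, adjusted p = 5.69e-06), miR-30c-1-5p (0.63 ± 0.08, in an intron of Nfyc on chromosome 4, 120769584 to 120769606), miR-378c-5p (0.54 ± 0.09), the red blood cell miRNA miR-144-3p (0.48 ± 0.14), let-7f-1-5p (0.45 ± 0.12), miR-133a-1-3p (0.40 ± 0.07), the lymphocyte miRNA miR-150-5p (0.36 ± 0.07; chromosome 7, 45121762 to 45121783) and miR-29b-2-3p (0.35 ± 0.11). Among arms with a mean of 20 CPM or more, the largest falls were in miR-501-3p (-1.03 ± 0.24, in an intron of Clcn5, chromosome X, 7241270 to 7241291), miR-99b-5p (-0.86 ± 0.16; chromosome 17, 17830194 to 17830215, in an intron of Spaca6), miR-212-5p (-0.79 ± 0.17), miR-100-5p (-0.77 ± 0.20; chromosome 9, 41531437 to 41531458) and miR-99a-5p (-0.71 ± 0.17; chromosome 16, 77598940 to 77598961, in an intron of Mir99ahg). miR-99a, miR-99b and miR-100 share their seed and repress Mtor. They were followed by miR-146b-5p (-0.67 ± 0.25) and miR-146a-5p (-0.64 ± 0.22), which restrain innate immune signalling, and by miR-221-5p (-0.52 ± 0.12), miR-125b-1-5p (-0.50 ± 0.11) and miR-145a-3p (-0.48 ± 0.13) of smooth muscle. Among the most abundant arms miR-22-3p rose (0.13 ± 0.03), miR-27b-3p (-0.21 ± 0.05) and miR-26a-2-5p (-0.11 ± 0.04) fell, and miR-133a-2-3p (-0.01 ± 0.03), miR-1a-1-3p (-0.25 ± 0.15) and miR-451a-5p (0.23 ± 0.12) were not called.

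Each of these calls ended when the library set entered the model: edgeR, the only tool run with that term, then called 0 of 346 arms (20 unadjusted), and 69 of the 121 slopes kept their sign. The slope of miR-208b-3p was then -0.21 ± 0.10, that of miR-29a-3p 0.26 ± 0.13, that of miR-29c-3p 0.08 ± 0.12, that of miR-127-3p -0.04 ± 0.09 and that of miR-99b-5p -0.30 ± 0.25, while that of miR-16-1-5p turned to -0.08 ± 0.13. Within set 1 alone, which held only 4 and 5 weeks, edgeR called 0 of 288 arms (14 unadjusted), with slopes of -0.25 ± 0.12 for miR-208b-3p and 0.35 ± 0.13 for miR-29a-3p. Sets 2, 4, 5 and 6 held fitted males of 1 age only, and set 3, with 1 male of 7 weeks beside 4 of 6 weeks, was not fitted alone. Counts of miR-16-1-5p, miR-30c-1-5p, miR-378c-5p, let-7f-1-5p, miR-133a-1-3p, miR-29b-2-3p, miR-125b-1-5p and miR-26a-2-5p are shared with other loci of the same or, for miR-378c-5p, a near-identical mature sequence and are uncertain by locus. Summed over arms that share bases 3 to 20, miR-16-5p (0.24 ± 0.05 per week) and miR-29b-3p (0.41 ± 0.11) rose, miR-378a-3p, miR-378b-3p and miR-378c-5p together rose (0.09 ± 0.03), and miR-125b-5p (-0.46 ± 0.10) fell. The sums of let-7f-5p (-0.03 ± 0.05), miR-133a-3p with miR-133b-3p (0.05 ± 0.03), miR-30c-5p (0.17 ± 0.07) and miR-26a-5p (-0.04 ± 0.03) were not called. From 6 to 8 weeks only, 38 arms were called and 20 of the 121 were among them. miR-208b-3p and miR-29a-3p were called there (-0.46 ± 0.08 and 0.37 ± 0.07), and miR-127-3p and miR-99b-5p were not (-0.32 ± 0.15 and -0.79 ± 0.25). Leaving out a single library ended the call of let-7f-1-5p (0.29 without male_8wk replicate 1), miR-144-3p (0.38 without male_8wk replicate 4, adjusted p = 0.0609), miR-29b-2-3p (0.28 without male_4wk replicate 1, 0.0649) and miR-146a-5p (-0.60 without male_4wk replicate 1, 0.0782, and -0.59 without male_8wk replicate 1, 0.0561). The call of miR-146b-5p ended without male_4wk replicate 1 or 2, male_5wk replicate 1 or 2, male_7wk replicate 1, or male_8wk replicate 1 or 3 (slopes from -0.62 to -0.70), and that of miR-26a-2-5p without male_4wk replicate 1, male_5wk replicate 2 or 3, or male_8wk replicate 1, 3 or 4 (-0.09 to -0.11).

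Among the lists, the Dlk1-Dio3 imprinted cluster on chromosome 12 (109572004 to 109743784), a run of maternally expressed miRNAs that is high before and shortly after birth, fell with age in males. Of its 20 tested arms 11 fell, 1 rose and 8 were not called, with the same counts adjusted over the list alone; 17 slopes were negative and the median was -0.18 (camera adjusted p = 0.00177; adjusted p = 0.375 with an estimated correlation and 0.320 with the library set as a term). miR-434-5p fell (-0.38 ± 0.08, adjusted p = 0.00119), as did miR-409-5p (-1.27 ± 0.28), miR-541-5p (-0.27 ± 0.07) and miR-300-3p (-0.20 ± 0.04), and miR-376b-5p rose (0.43 ± 0.12); these 5 were chosen after their values were seen. The cluster took 0.362% ± 0.00981 (n = 2) of counts at 4 weeks and 0.167% ± 0.0289 (n = 4) at 8 weeks. In the fibroblast and matrix list 6 of 16 arms rose, all of the miR-29 family, and 1 fell, miR-199a-2-3p (-0.13 ± 0.04); adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.171). The sum of miR-199a-1-3p, miR-199a-2-3p and miR-199b-3p, which have one mature sequence, was not called (-0.08 ± 0.04, adjusted p = 0.145). In the X chromosome list 3 of 32 rose and 10 fell (the same over the list alone, camera adjusted p = 0.342). Among the latter was miR-351-5p (-0.47 ± 0.09, edgeR adjusted p = 0.000364, chromosome X, 53053315 to 53053338), while its neighbour miR-322-5p was not called (-0.12 ± 0.05). By fry, which does not compare a list with other arms, the Dlk1-Dio3 cluster (fry adjusted p = 0.000152) and the X chromosome list (0.00834) fell. The fibroblast and matrix list rose by fry (0.000171). The fry test was not run with the library set as a term.

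The remaining 13 lists were not called in males in the main test. With the library set as a term camera called the liver and brain list, the let-7 list and, with its sign turned, the fat tissue list. Of the arms of these 13 lists, miR-155-5p, miR-221-3p, miR-222-3p, miR-296-5p, miR-455-3p and miR-141-3p were chosen after their values were seen. In the muscle list 2 of 13 arms rose, both of miR-133a-1, and miR-208b-3p fell. Of the red blood cell list 1 of 7 rose, miR-144-3p. In the white blood cell list miR-150-5p and miR-155-5p (0.24 ± 0.04) rose, miR-146a-5p fell, and 4 of 7 arms were not called. Among endothelial arms miR-126a-3p (0.17 ± 0.04), miR-221-3p (0.18 ± 0.04) and miR-222-3p (0.28 ± 0.07) rose, and miR-221-5p and miR-296-5p (-0.37 ± 0.11) fell, of 6. A single arm changed in each of the smooth muscle list (1 of 4, miR-145a-3p fell), the fat tissue list (1 of 6, miR-455-3p rose by 0.28 ± 0.09) and the epithelial and lung list (1 of 4, miR-141-3p fell, -0.45 ± 0.13), and 0 of 5 in the liver and brain list. Over the list alone these 8 lists gave the same counts. In the let-7 family 4 of 23 rose and 3 fell (3 and 1 adjusted over the list alone), in the miR-17 to miR-92 clusters 1 of 15 rose (0 over the list alone), in the miR-15 and miR-16 family 4 of 13 rose and 2 fell, in the miR-30 family 2 of 12 rose and 1 fell, and in the hypertrophy and stress list 2 of 31 rose and 5 fell, the last 3 with the same counts over the list alone.

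In females miRNA level was compared with age from 6 to 9 weeks over 16 libraries. miR-208b-3p fell here as well, from 1189 ± 290 CPM (SD, n = 6) at 6 weeks to 528 ± 42.5 (n = 5) at 9 weeks, with all 5 libraries of 9 weeks (486 to 581) below all 6 of 6 weeks (804 to 1423); its slope was -0.40 ± 0.10 (edgeR adjusted p = 0.0366). miR-199b-5p, a miRNA tied to calcineurin signalling in the heart (chromosome 2, 32318485 to 32318507), fell from 80.2 ± 12.9 CPM to 39.9 ± 3.72 (-0.32 ± 0.08, adjusted p = 0.0366). miR-434-3p of the Dlk1-Dio3 cluster (chromosome 12, 109594565 to 109594586) fell from 86.9 ± 24.0 to 32.6 ± 2.93 CPM (-0.45 ± 0.12, adjusted p = 0.0496), and miR-330-5p (chromosome 7, 19181486 to 19181507, in an exon of Eml2) from 33.5 ± 4.46 to 23.5 ± 1.90 (-0.17 ± 0.04). miR-3057-5p (chromosome 10, 81271610 to 81271633, in an exon of Apba3) rose from 27.0 ± 4.19 to 50.2 ± 8.03 CPM (0.28 ± 0.06, adjusted p = 0.0366). For each of the last 4 arms all 5 libraries of 9 weeks lay on one side of all 6 of 6 weeks. Not called were miR-29a-3p (0.12 ± 0.07), miR-208a-3p (-0.02 ± 0.10), miR-499-5p (0.03 ± 0.10), miR-133a-2-3p (-0.03 ± 0.09) and miR-1a-2-3p (0.53 ± 0.15, adjusted p = 0.0542).

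edgeR called 10 of 331 arms in females, 1 rising and 9 falling (64 unadjusted); DESeq2 called 48 and limma-voom 25, and both called all 10. The 5 other arms had a mean under 20 CPM and all fell: miR-296-5p, miR-337-5p, miR-298-5p, miR-18a-5p and miR-362-3p, named after their values were seen. The call rested on single libraries: 0 arms were called without female_6wk replicate 2, 3, 4 or 5 or female_9wk replicate 3 or 4, 1 without female_9wk replicate 1, 2 or 5, 6 without female_6wk replicate 1, 23 without female_8wk replicate 1 and 75 without female_8wk replicate 2. All 5 libraries of 9 weeks formed a library set of their own; with the set as a term edgeR called 0 (17 unadjusted), the slope of miR-208b-3p was -0.04 ± 0.15, and that of miR-199b-5p turned to 0.14. Among other settings for the sets, 5 placed the libraries of 9 weeks with libraries of 6 weeks, of which 3 called 151 arms and 2 called 0.

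2 lists were called in females. All 7 tested red blood cell arms had positive slopes, with a median of 0.17 (camera adjusted p = 0.00104; adjusted p = 0.0282 with an estimated correlation); none was called over all arms, and 2 rose adjusted over the list alone, miR-486a-5p (0.53 ± 0.15) and miR-486b-5p (0.57 ± 0.16). Red blood cell miRNAs took 8.70% ± 2.48 (n = 6) of counts at 6 weeks, 6.42% ± 1.37 (n = 3) at 7 weeks and 18.1% ± 1.90 (n = 5) at 9 weeks. The 2 libraries of 8 weeks had 7.37% and 40.5%, the latter in female_8wk replicate 2, and without that library the camera adjusted p of the list was 0.00778. The share sums counts and so follows its most abundant arms, and it does not show how far the other arms rose. At 6 and 9 weeks muscle miRNAs took 9.93% ± 1.75 and 7.61% ± 0.881. In the Dlk1-Dio3 cluster 2 of 16 arms fell (5 adjusted over the list alone), 15 slopes were negative and the median was -0.14 (adjusted p = 0.000814; adjusted p = 0.0673 with an estimated correlation). miR-127-3p, its most abundant arm, had a slope of -0.06 ± 0.09 in females and was not called. Of the 16 arms tested in both sexes 14 had negative slopes in both. With the library set as a term neither list was called: the red blood cell list turned downward (adjusted p = 0.349), and the Dlk1-Dio3 cluster had an adjusted p of 0.861.

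**Figure D4:**
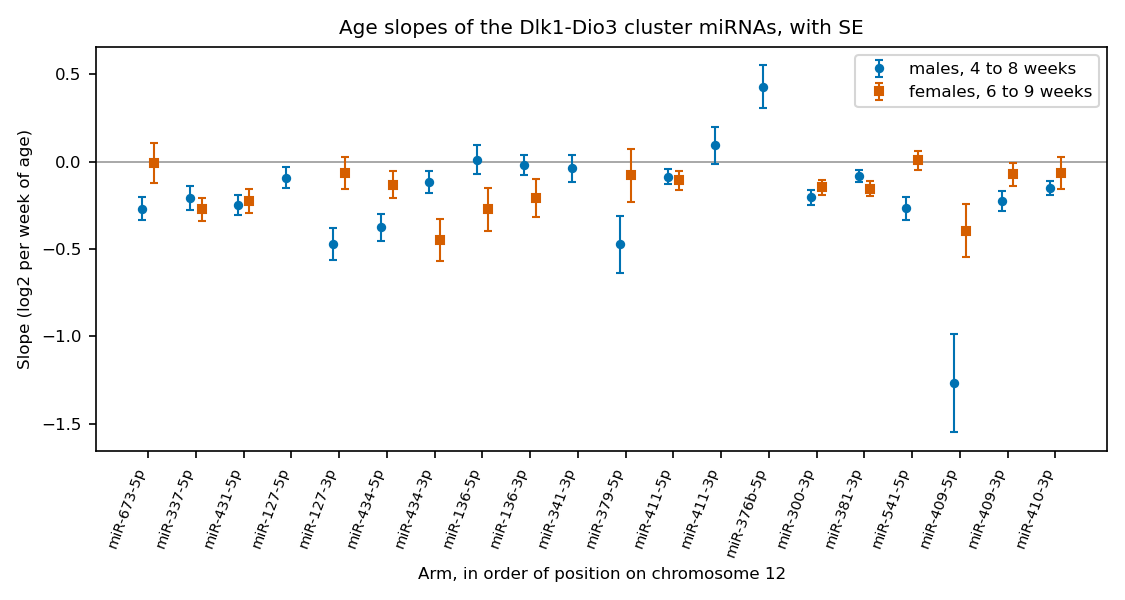
Slope of level on age (log2 per week ± SE) for each tested arm of the Dlk1-Dio3 cluster, ordered by position on chromosome 12, in males from 4 to 8 weeks and females from 6 to 9 weeks. In males 17 of 20 slopes and in females 15 of 16 lay below 0.

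In the other 14 lists females had few called arms. A single arm fell in each of the muscle list (miR-208b-3p; adjusted over the list alone 1 rose and 1 fell), the endothelial list (miR-296-5p), the fibroblast and matrix list (miR-199b-5p), the miR-17 to miR-92 clusters (miR-18a-5p; 2 over the list alone) and the X chromosome list (miR-362-3p). In the hypertrophy and stress list 2 of 31 fell, miR-208b-3p and miR-199b-5p. No arm was called in the white blood cell, smooth muscle (1 fell over the list alone), fat tissue, epithelial and lung, liver and brain, let-7, miR-15 and miR-16, and miR-30 lists. The smallest camera adjusted p among the 14 was 0.0787, for the X chromosome list.

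The slopes of the sexes were compared directly over 6 to 8 weeks. The 7 arms called had slopes that differed by 0.48 to 0.96 log2 per week in size. miR-3102-3p, in its form starting at 100882307 on chromosome 7 in an exon of Arhgef17, had slopes of 0.86 ± 0.20 in females and -0.11 ± 0.06 in males, a difference of 0.96 ± 0.19 (edgeR adjusted p = 0.00741). miR-208a-5p, the less abundant arm of the Myh6 hairpin, had slopes of 0.47 ± 0.13 and -0.15 ± 0.08. The female slope was also the higher for let-7d-3p (0.82 against 0.07), miR-125a-5p (0.38 against -0.18), miR-744-5p (0.37 against -0.12) and miR-30d-5p (0.32 against -0.17), and lower for miR-199a-2-3p (-0.59 against -0.09). With copies of one mature sequence summed, 3 of the 7 were not called: miR-199a-3p with miR-199b-3p (-0.44 ± 0.13, adjusted p = 0.0607), and miR-744-5p (0.0600) and miR-30d-5p (0.0607), which have no such copy. miR-208b-3p was not called (difference -0.40 ± 0.18, adjusted p = 0.175), nor was miR-29a-3p (-0.03 ± 0.16). edgeR called 7 of 346 arms (77 unadjusted), DESeq2 25 and limma-voom 1. The count was 0 when scaled by total counts (31 unadjusted) and 94 with the library set as a term, which included all 7. It was 0 with 8 sets (12 unadjusted), where let-7d-3p and miR-744-5p turned sign (-0.034 and -0.063), and 0 in 2 of 18 settings for making the sets. Without the 4 libraries dominated by 1 arm the count was 1. It was 1 without male_8wk replicate 2, 3 or 4, female_6wk replicate 4 or female_8wk replicate 2, 21 without male_8wk replicate 1, 20 and 17 without female_6wk replicate 1 and 6, 11 without female_7wk replicate 2 and 89 without female_8wk replicate 1.

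How far a miRNA varied between libraries of one sex and age was measured at 6 weeks, over the arms with a mean of 100 CPM or more. miR-146b-5p (coefficient of variation, CV, 139%), miR-146a-5p (127%), miR-24-2-3p (111%), miR-143-3p (104%) and miR-144-5p (93.1%) varied most between the 12 male libraries. The miR-24-1 hairpin holds the same bases 3 to 20 as miR-24-2-3p, so its counts are uncertain by locus. miR-24-1-3p had a CV of 30.8%, and the sum of both had 61.3% (22.9% within library sets), with 16.0% to 56.2% of the sum at miR-24-2. The 5 least variable arms were miR-181d-5p (4.88%), miR-181c-3p (6.35%) and miR-181c-5p (6.59%), which lie together in an intron of Nanos3 on chromosome 8, let-7c-1-5p (7.40%) and miR-130a-3p (7.47%). The median CV was 18.9% in males and 19.5% in females, against 1.43% and 1.33% from counting alone, and 21 arms exceeded 50% in males. Within library sets the medians were 11.4% and 8.71%, and the CVs of miR-146b-5p, miR-146a-5p and miR-24-2-3p were 60.6%, 49.8% and 34.0%, while those of miR-143-3p and miR-144-5p were 112% and 94.2%. miR-143-3p was far above the other libraries in male_6wk replicates 2 and 6, and miR-144-5p in male_6wk replicate 4 (1163 CPM against a median of 232 in its set). Across arms, which are not independent replicates, the CVs of the sexes had a Spearman rho of 0.82.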

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

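The tests of the miR-143 and miR-378a hairpins were chosen after their levels had been seen. Single libraries are named here where, in a group of 4 to 10 libraries, they stood apart from the rest by the gap criterion of Dixon. Groups of that size were male_8wk, female_6wk and female_9wk. That criterion marked 13 values over 120 tests, each of 1 quantity in 1 group, where chance alone marks about 1 in 20. The tests used the same libraries and were not independent.

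miR-143-3p reached 555180 CPM in female_6wk replicate 1, where the 5 other libraries of the group held 86872 to 138500, and smooth muscle miRNAs took 43.7% of its counts against 11.04% to 13.7%. In the same library miR-378a-3p stood at 46806 CPM (34866 to 39048 in the others of the group), inside the range of the other libraries of its set (37666 to 52872). X chromosome miRNAs took 0.199% of its counts (0.315% to 0.380% in the others of the group), and hypertrophy and stress miRNAs took 0.981% (1.64% to 1.78%). These 2 shares follow in large part from the counts taken by miR-143-3p: over the counts other than miR-143-3p they were 0.353% (0.354% to 0.439%) and 1.74% (1.85% to 2.06%).

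The miR-143 hairpin was as high in male_6wk replicates 2 and 6, and the miR-378a hairpin in female_7wk replicate 2, where miR-378a-3p was 16.0-fold above the median of its library set. Smooth muscle or vessel tissue in the sample would raise miR-145a too, the neighbour cut as a separate hairpin from the same transcript as miR-143. The median log2 difference of the miR-145a arms from the set, however, was -0.042 against 2.62 to 2.66 for miR-143-3p. Amplification or capture of a single sequence would leave the other arm at its usual level, and the smallest log2 difference of the other arm over the 4 libraries was 2.80; a general change of the library would move many arms, and at most 3 arms other than the hairpin and its relatives lay over 4-fold from the set (miR-10b-5p, miR-19b-2-3p and Gm24270-5p, all lower, in female_7wk replicate 2, named after their values were seen). The relatives miR-378b-3p (11.02-fold), miR-378c-5p (11.6-fold) and miR-378d-5p (9.23-fold) were high in that library too. They held 229, 614 and 668 CPM there, beside 661900 CPM of miR-378a-3p. The mature sequences of miR-378b-3p and miR-378c-5p are near-identical to that of miR-378a-3p, so their counts are uncertain by locus. Their rise therefore does not show that these loci themselves were higher. Whether reads of miR-378a-3p were also counted at miR-378d-5p was not tested. What stays open is more of the whole hairpin in the RNA, which may come from the animal or from mixing with another sample; neither was tested, the labels call all mice wild type, and no biological explanation other than smooth muscle or vessel tissue was tested.

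Other libraries stood apart in single values. In male_8wk replicate 3 muscle miRNAs took 11.6% of counts (10.6% to 10.8% in the others of the group, 9.46% to 16.2% in the others of its library set). In male_8wk replicate 1 miR-133a-1-3p was at 23554 CPM (11260 to 12724 in the others of the group), miR-499-3p at 28.8 CPM (10.3 to 13.0), and liver and brain miRNAs took 0.0392% (0.0216% to 0.0226%). This was the only male of 8 weeks in set 5, and the 3 other libraries of that set, all female, held 19990 to 23590 CPM, 17.4 to 24.7 CPM and 0.0278% to 0.0391%. In female_6wk replicate 6 liver and brain miRNAs took 0.0406% (0.0159% to 0.0192% in the others of the group) and the miR-17 to miR-92 clusters 0.711% (0.428% to 0.486%). The 7 other libraries of its set had medians of 0.0375% and 0.684%, and the only other female of 6 weeks among them was replicate 1, dominated by miR-143-3p. The values of both libraries thus lay nearer to those of their set than to those of their group. miR-208a-3p was at 1428 CPM in female_6wk replicate 4 (864 to 1074), and miR-1a-1-5p at 9.23 CPM in female_9wk replicate 2 (5.12 to 6.31).

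For 7 arms the slope on age over 6 to 8 weeks differed between the sexes by edgeR's test of the difference itself. The female slope had only 2 libraries of 8 weeks. The count went to 89 without female_8wk replicate 1, and to 1 without female_8wk replicate 2, which held 66 arms over 4-fold from its set median. Female minus male differences were 0.96 log2 per week for miR-3102-3p, 0.75 for let-7d-3p, 0.61 for miR-208a-5p, 0.55 for miR-125a-5p, 0.48 for miR-744-5p, 0.48 for miR-30d-5p and -0.50 for miR-199a-2-3p; the last 3 were not called with copies of one mature sequence summed (adjusted p = 0.0600 to 0.0607). Of 100 splits of the libraries, the real one included, 19 called at least 7 arms, and the highest of the others called 46, so chance cannot be excluded for this count.

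The library of 16 weeks entered no test. Of 349 arms, 108 lay outside the range of the 22 males of 4 to 8 weeks, 39 above and 69 below, whereas single males of 4 to 8 weeks had a median of 30 arms outside the range of the rest and at most 61. miR-208b-3p stood at 187 CPM, miR-29a-3p at 4326 CPM and miR-127-3p's neighbours miR-136-3p and miR-136-5p at 17.9 and 7.82 CPM, against a lowest value of 47.3 and 19.5 CPM in the younger males; the miR-136 arms were chosen after their values were seen. Red blood cell miRNAs took 24.98% of its counts, against at most 16.2% in any of the 22 younger males. Of these, miR-486b-5p (146450 CPM) and miR-486a-5p (114750 CPM) lay above the highest younger males (79079 and 73212 CPM). The red blood cell miRNA miR-144-5p lay below all of the younger males, at 88.843 CPM. The share therefore does not show that red blood cell miRNAs were high as a class. With 1 library of this age, these values have no replicate check.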

How the results depend on the processing

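The settings that use library sets, summed copies, a GC trend or fewer libraries by set, and those without the 4 libraries dominated by a single arm, were chosen after seeing the data; the rest were planned. For single arms and lists, the planned settings other than leaving out a library gave 3421 values. Of these 3001 stayed, 131 lost the call, 66 gained it, 218 moved and 5 turned sign. A called value stayed if it was called again in the same direction. An arm not called stayed if it lay within 1 SE of its main value (a share within 1 SD), whatever its sign, and moved otherwise. Where the unit of the slope changed, its sign decided. A list not called stayed if it was again not called. A turned sign was counted only where the main or the other setting gave a call. The added settings gave 2417, with 1413, 159, 76, 691 and 78. Leaving out 1 library gave 5853 values, of which 5624 stayed, 124 lost and 41 gained the call, 64 moved and 0 turned sign. For the lists, where this was added later, it gave 896 values, of which 885 stayed. The cause was not tested for any change given here, except that a filter at 50 CPM tests fewer arms and a shorter age range uses fewer libraries. Counting alone limits low arms most: 3 counts are 1.68 CPM in the shallowest library, female_8wk replicate 2. At 6 weeks, where that library was not fitted, the interval of the sex difference lay within 1 log2 unit of 0 for 297 of 339 arms. Whether the remaining arms were low ones was not tested. An analysis with all features beside miRNA was not run, since the files held no other class.

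For the sexes, edgeR called 0 arms at 6 weeks (25 unadjusted) and 0 over 6 to 8 weeks (46 unadjusted) under all settings and left-out libraries but 3: the replicate block called 2 at 6 weeks (0 higher, 2 lower in females) and 2 over 6 to 8 weeks (1 and 1), and the library set with copies summed called 1 over 6 to 8 weeks. DESeq2 called 0 and 0 (31 and 54 unadjusted), limma-voom 0 and 0 (25 and 40). The replicate numbers did not pair the libraries: same-number pairs across groups had a median correlation of -0.05 (81 pairs, 26 over 0.1) against 0.00 for other pairs (480), so the block results are counts of calls only. With the block the female slopes gave 0 calls (52 unadjusted), the slope differences 0 (71 unadjusted) and the male slopes 95. The highest such correlation was 0.726 between libraries of different numbers and 0.397 between those of one number, so not every library correlated best with its own number. These values are not correlations of the levels themselves, which ran from 0.864 to 0.998 between libraries.

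In males the 121 calls went to 100 (without male_8wk replicate 3) and 125 (without male_6wk replicate 4) at the extremes of leaving out 1 library. They were from 91 to 153 with RLE factors (115), total counts (96), DESeq2 (128), limma-voom (117), no filter (105), depth as a covariate (121), a surrogate variable (153), copies summed (104), the dominated libraries left out (113), a GC trend removed (126) and log2 age (91). The filter at 50 CPM gave 75 (35 rising, 40 falling), 6 to 8 weeks only 38 (25 and 13) and 4 to 16 weeks 65 (29 and 36). edgeR called 0 with the library set (20 unadjusted), with the set and copies summed (15), with 6 sets (28), 8 sets (20) and looser sets (12), and in set 1 alone (14); over 18 settings for making the sets, which gave 7 different groupings (8 settings had the main membership), it called 0 in all 18.

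Signs of called male slopes that turned are given only for the arms to be named by the rule, and other called slopes turned too. The order is library set, set with copies summed, 6 sets, 8 sets, looser sets and set 1 alone. miR-125b-1-5p went to 0.22, 0.24, 0.24, 0.22, 0.32 and 0.33, and miR-144-3p to -0.42, -0.42, -0.69, -0.42, -0.44 and -0.66. miR-16-1-5p went to -0.080, -0.10, -0.21, -0.080, -0.11 and -0.12; miR-16-2-5p to -0.096, -0.10, -0.13, -0.096, -0.19 and -0.089. miR-199a-2-3p went to 0.20, 0.20, 0.20, 0.20, 0.13 and 0.28, miR-26a-2-5p to 0.078, 0.072, 0.10, 0.078, 0.080 and 0.10, miR-27b-3p to 0.14, 0.13, 0.14, 0.14, 0.13 and 0.22, and miR-29b-2-3p to -0.38, -0.37, -0.36, -0.38, -0.26 and -0.62. miR-146a-5p went to 0.080, 0.064, 0.13, 0.080 and 0.13 in the first 5, and miR-126a-3p to -0.040 (library set), -0.049 (copies summed), -0.040 (8 sets) and -0.16 (set 1). With 6 sets miR-127-3p went to 0.027, miR-133a-1-3p to -0.040, miR-146b-5p to 0.00183 and miR-30c-1-5p to -0.014, and with looser sets miR-145a-3p to 0.10, miR-212-5p to 0.063 and miR-99a-5p to 0.072. let-7f-1-5p went to -0.026 with copies summed, and miR-26a-2-5p to 0.022 over 6 to 8 weeks only.

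In females the 10 calls ranged from 0 (without female_6wk replicate 2) to 75 (without female_8wk replicate 2). They were 9 with total counts and with robust dispersion, 11 with copies summed and 7 without the dominated libraries. They were 2 with RLE factors, 48 with DESeq2, 25 with limma-voom, 1 with no filter, 5 with the filter at 50 CPM, 54 with depth as a covariate, 67 with a surrogate variable, 1 with the 5 most abundant arms left out, 35 with a GC trend removed, 93 for 9 against 6 weeks and 16 over 6 to 8 weeks only. edgeR called 0 with the library set, 6 sets and 8 sets (17 unadjusted each) and with the set and copies summed (20), and 151 with looser sets; it called 0 in 16 of the 18 settings for the sets. miR-199b-5p went to 0.14 (library set, 6 sets, 8 sets), 0.15 (set with copies summed) and 0.049 (6 to 8 weeks), and miR-434-3p to 0.000523 (set with copies summed) and 0.10 (6 to 8 weeks). Some arms not called over 6 to 9 weeks were called with the other sign: miR-150-5p (0.76) and miR-92a-1-3p (0.52) over 6 to 8 weeks, and miR-128-2-3p (0.14), miR-133a-1-3p (-0.21) and miR-133a-1-5p (0.090) with looser sets.

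The 7 slope differences between the sexes ranged from 1 (without male_8wk replicate 2) to 89 (without female_8wk replicate 1). The count was 5 with RLE factors and 7 with robust dispersion, 0 with total counts (31 unadjusted) and with depth as a covariate (45), 25 with DESeq2, 1 with limma-voom, 1 with no filter, 19 with the filter at 50 CPM, 18 with a surrogate variable, 4 with the 5 most abundant arms left out, with copies summed and with a GC trend removed, and 1 without the dominated libraries. It was 94 with the library set and with looser sets, 75 with the set and copies summed, and 99 with 6 sets. Over the 18 settings for the sets it was at most 104, and 0 in 2 of them. With 8 sets it was 0 (12 unadjusted), where let-7d-3p went to -0.034 and miR-744-5p to -0.063.

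Of the lists, the 1 called between the sexes was not called with an estimated correlation, by fry, with the library set, with copies summed or without the dominated libraries (0 each), and its adjusted p with the set was 0.775. Leaving out 1 library gave 0 to 1 called lists between the sexes, 1 to 2 in males (2 without male_4wk replicate 2) and 2 to 4 in females (4 without female_6wk replicate 1). In males camera called 1 list, 0 with an estimated correlation, 3 by fry and 3 with the library set, where the fat tissue list turned sign (adjusted p = 0.0496) and the liver and brain (0.00642) and let-7 (0.0242) lists were called. In females 2 lists became 1 with an estimated correlation and 0 with the set, where the red blood cell list turned sign (0.349). The shares of lists at 6 weeks gave 0 calls in each of the settings run, those within library sets included. Median, mean and test differed in sign, for lists not called, in the white blood cell, endothelial, smooth muscle, fibroblast, fat tissue and let-7 lists between the sexes, in the white blood cell, endothelial, epithelial and let-7 lists in males, and in the endothelial, smooth muscle, fibroblast, liver and brain and miR-17 to miR-92 lists in females. The median CV at 6 weeks was 25.3% in males and 23.4% in females on total counts and 11.4% and 8.71% within library sets. Leaving out 1 library gave 16.9% (male_6wk replicate 8) to 19.8% (male_6wk replicate 7) and 15.9% (female_6wk replicate 1) to 20.3% (female_6wk replicate 5).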

Other observations

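The tests in this part were chosen after the results were seen, except the splits of the libraries. miR-99 and miR-100 repress Mtor and sit in 3 related clusters beside let-7 genes. They were taken up because they were among the largest male falls, so lower ratios to less changed neighbours follow in part from that choice, and the ratios are given as values with no test. In the 22 males of 4 to 8 weeks the log2 ratio of miR-99b-5p to let-7e-5p, its neighbour on chromosome 17 (17830366 to 17830386), had a slope of -0.80 ± 0.14 per week (SE). It was -0.64 ± 0.17 for miR-99a-5p to let-7c-1-5p on chromosome 16 (77599672 to 77599692), and -0.95 ± 0.21 for miR-100-5p to let-7a-2-5p on chromosome 9 (41536732 to 41536753). Against the other arm of the hairpin the slope was -0.81 ± 0.15 for miR-99b-5p and -0.81 ± 0.23 for miR-99a-5p. With the library set as a term the 5 slopes were -0.33 ± 0.31, -0.37 ± 0.36, -0.40 ± 0.33, -0.43 ± 0.34 and -0.15 ± 0.33.

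The X chromosome cluster that holds miR-322, miR-503, miR-351, miR-542 and miR-450, known from muscle differentiation and from the cell cycle, had 5 arms that fell with age in males; its arms were chosen after their values were seen. By edgeR miR-322-3p (-0.30 ± 0.06 per week, adjusted p = 0.00134; chromosome X, 53054269 to 53054289), miR-503-3p (-0.24 ± 0.05), miR-542-3p (-0.36 ± 0.09) and miR-450a-2-5p (-0.32 ± 0.09) fell beside miR-351-5p; none was called with the library set as a term, where 0 of 346 arms were (20 unadjusted). The arms miR-322-5p (-0.12 ± 0.05), miR-542-5p (0.00 ± 0.07), miR-450a-1-5p (-0.09 ± 0.09) and miR-450b-5p (0.00 ± 0.04) were not called.

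Ages and library sets were closely bound: over the 38 libraries up to 9 weeks, 92.2% of the variance of age lay between sets. A batch of preparation or processing may therefore account for the age slopes as well as age itself. In males edgeR called 121 arms, and 1 of 100 splits of the libraries, the real one, reached that count; the highest other split called 94, so chance is excluded as far as such splits go, which ignore the library sets (92.8% of the variance of the real split lay between sets, a median of 21.4% of the others), and a split that calls 94 points to a structure of the samples. Over the 38 libraries of both sexes up to 9 weeks, the slopes of the 121 arms amounted to 0.535 ± 0.134 (jackknife SE) of the male slopes without the set and to 0.179 ± 0.178 with it, and in males alone to 0.113 ± 0.229 with it; with the set the median SE of a slope also rose from 0.0617 to 0.137, and library set and age cannot be told apart for these arms. GC content of the mature sequence as the whole cause is argued against, since 108 of the 121 arms were still called in the same direction after a GC trend per library was removed. A change with age stays open.

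The slopes of arms that share bases 3 to 20 with arms of other loci were weighed apart. If reads shared between copies were the cause, the sum over the loci would not change with age. Of 20 such arms called in males, the sum was called in the same direction for 10, as for miR-125b-5p and miR-16-5p, and was not for the rest, as for let-7f-5p and miR-26a-5p. The 20 arms are not 20 separate sums. Both copies of miR-125b-5p, miR-16-5p, miR-29b-3p and miR-26a-5p were among them, as were miR-378b-3p and miR-378c-5p of another sum. Reads shared between copies and a change of the miRNA itself therefore cannot be told apart over these arms as a set.

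For the other comparisons the splits gave the following. In females 1 of 100 splits, the real one, called as many as 10 arms, with 3 as the highest of the others. Chance is excluded for that count only as far as splits that ignore the library sets can show: 94.8% of the variance of the real split lay between sets, against a median of 29.6% for the others and 61.7% to 72.04% for the 3 others with any call. The count was also 0 without female_6wk replicate 2, 3, 4 or 5 or female_9wk replicate 3 or 4. For the sex difference edgeR called 0 arms in the real split, a count that all 100 of 100 splits reach by construction at 6 weeks and over 6 to 8 weeks, so the splits decide nothing there. The highest other splits called 106 arms at 6 weeks and 66 over 6 to 8 weeks, which points to a structure of the samples. Of the variance of these splits 46.7% and 25.01% lay between library sets, against a median of 15.8% and 13.8% over the other splits and 29.2% and 27.0% for the real ones. At 6 weeks the 5 splits with 27 or more calls lay at 32.5% to 46.7%, and another split with 59.2% called 0, so whether the library sets are that structure stays open.

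Some libraries held further values apart from their library set. In male_6wk replicate 4 the red blood cell miRNAs miR-144-3p (2072 CPM against a set median of 390), miR-144-5p (1163 against 232) and miR-451a-5p (16271 against 3564) were high together. In female_8wk replicate 2, the library of lowest depth, 66 arms lay over 4-fold from the set median and miR-486b-5p took 22.5% of the counts.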
